A study of Mus musculus with 2 samples.

How the data were processed

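The data were 2 droplet single-cell RNA libraries from the thoracic aortas of male C57BL/6 mice that were 24 weeks old, 1 library per genotype. The mice carried Myh11-CreERT2, a tamoxifen-inducible recombinase active in smooth muscle cells (SMCs), and the mT/mG reporter, which switches a cell from membrane tdTomato to membrane eGFP once the recombinase has acted. The control mice were labelled Tsc1+/+, and in the mice labelled knockout (KO) the recombinase was also meant to delete floxed Tsc1. Tamoxifen was given at an age of 1.5 weeks. Per the labels' protocols, aortas were digested with collagenase and elastase at 37 °C, viable GFP-positive cells were sorted, and libraries were made on the 10x Chromium platform and sequenced on an Illumina HiSeq instrument. How many animals went into each library is not given in the sources used here.

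For each library the authors deposited a matrix of raw UMI counts (unique molecular identifiers, so that PCR copies of 1 molecule count once) per gene and cell. Per the submitters' processing notes, bcl2fastq, Cell Ranger and Seurat 2.0 were used with the mouse build mm10, and the versions of the first 2 tools are not given in the sources used here. The matrices hold 28000 features, of which 27998 have Ensembl identifiers and 2 are the transgenes eGFP and tdTomato. They hold 2095 control cells with 21690868 UMIs and 2097 KO cells with 32427513 UMIs. How the authors called cells among all barcodes is not given in the sources used here. The third deposited table, of the authors' own averages, lists 16415 genes in 16 columns, each named by a cluster number and a library. From the values, each column sums to 10000, so the unit was taken as mean counts per 10000 on a linear scale. Gene positions came from a GENCODE annotation of the same build, in which 27645 of the 27998 identifiers were found.

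Cells were kept with at least 500 genes detected and at most 10% of UMIs from mitochondrial genes, limits set before the data were examined. This left 2042 control cells with 21445606 UMIs and 1936 KO cells with 30865721 UMIs. All 53 removed control cells and all 161 removed KO cells were over the mitochondrial limit, and 1 of the KO cells was also under the gene minimum. Kept cells of both libraries were clustered together without integration, on log counts scaled to the median total, with 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 0.5. Scrublet, run per library, called 5 control and 8 KO cells doublets. They stayed in the main values and were left out in an alternative.

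Clusters were named from marker genes fixed before the data were examined, by a scoring rule set afterwards. A name other than SMC needed 1 marker among the 10 leading genes of a cluster, and at least 3 markers, making up no less than 50% of that name's markers, at 50 CPM or more and at 2 or more times their level in all other cells. SMC-like needed the same share of SMC markers at 50 CPM, and no more leading genes from another type's markers than from SMC markers. All other clusters stayed unnamed. Clusters with at least 1000 CPM of eGFP were called eGFP-positive, a limit also set after the data were seen, and the levels on either side of it lay far apart.

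With 1 library per group there was no test, no p-value and no replicate check. Per gene, deposited counts were summed over the cells of a population in each library and divided by the total to give CPM. The KO to control ratio of CPM was given with the exact conditional binomial 95% interval of a ratio of Poisson counts. Counts got exact Poisson intervals and shares of cells exact binomial (Clopper-Pearson) intervals. All intervals cover counting error only, not differences between animals or preparations. Where the control count was 0, the ratio was set against a floor of 3 counts and given as at least that size. A gene was listed as higher or lower when the ratio was at least 1.5 or at most 1/1.5, among genes with at least 50 CPM in at least 1 library. Depth limits the small end: 3 counts equal 0.140 CPM in the control library and 0.0972 CPM in the KO library.

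The named genes followed a rule fixed before the data were examined: Tsc1, the 12 largest and the 12 smallest ratios at 50 CPM or more (leaving out mitochondrial and ribosomal protein genes and unnamed gene models), of each gene list's members at 10 CPM or more, up to 3 at either end and any changed 2 or more times, markers of each cell type that names a cluster, sex-linked genes, and the 5 most abundant genes per library. Some genes that the rule picks are not reported here. Genes outside it are named only as leading genes that describe a cluster, and these were chosen after their values were seen. The 27 gene lists were fixed at the same time: SMC contractile, elastic fiber and matrix, lysosome and CLEAR network, MiT transcription factors, autophagy, phagocytosis and efferocytosis, matrix proteases and inhibitors, modulated SMC and osteochondrogenic, melanocytic and osteoclast MITF targets, glycolysis and pentose phosphate, sterol synthesis, fatty acid synthesis, ATF4 targets and amino acid synthesis, unfolded protein response and chaperones, NRF2 targets, translation factors, oxidative phosphorylation, mTOR pathway components, TGF-beta signaling and targets, inflammation, antigen presentation and interferon, SMC growth factor and vasoactive receptors, dissociation stress and immediate early, cell cycle, aortic position, ribosomal proteins, and mitochondrially encoded genes. For each list the median log2 ratio of members with at least 5 CPM in at least 1 library was set against 10000 random lists of the same size, each member replaced by 1 of the 100 genes nearest in mean CPM, and its percentile describes these libraries only. A percentile of 0 or 100 means below or above all of them. A member with 0 control counts entered the median at its bound.

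Shares of cells with at least 1 UMI were given for all cells and after thinning each cell to 5000 UMIs, the 10th percentile of totals over kept cells rounded down. This left out 363 control and 31 KO cells with fewer UMIs, of which 95 and 20 were in eGFP-positive clusters. All kept cells were the main population and SMC-like clusters the second, as fixed before the data were examined. The eGFP-positive clusters and the pairs of clusters 2 and 1, 3 and 1, and 6 and 4 were added after the data were seen, as was a comparison of cells matched on UMI totals, with the same number of cells of each library in each bin of 1000 UMIs. So were cells of clusters 2 and 1, and of clusters 3 and 1, matched on thinned UMIs of Hspa1a and Hspa1b, with the same number of each library at each count. Other settings fixed in advance were looser and stricter cell filters, TMM and median-of-ratios scaling, totals without mitochondrial and ribosomal genes, equal weight per cell, thinning, removal of doublets or of the deepest cells, other minimum levels and folds, and other clusterings.

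The ratio and list calculations were tested on simulated data drawn from the mean of the control and KO levels at both library sizes, for all kept cells, with 200 of 28000 genes changed. None (0%) of the genes changed 1.25-fold were listed, and 100% of those changed 2-fold and 100% of those changed 4-fold were. Of 2529 unchanged genes at the minimum level 0 were listed, and the 95% interval covered the true ratio for 95.7% of genes. The oxidative phosphorylation list, raised 1.25-fold, gave a median log2 ratio of 0.31 at percentile 100. The draws were Poisson counts with no variation between animals or preparations, so they check the calculation only and not how often real libraries would differ. Tools were Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, leidenalg 0.10.2, scikit-learn 1.9.0 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 for the TMM factors.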

Results

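Aortic SMCs marked by eGFP at 1.5 weeks of age were compared at 24 weeks between mice labelled Tsc1+/+ and mice labelled as Tsc1 KO in SMCs. Tsc1 encodes hamartin, which acts with tuberin to restrain the growth kinase complex mTORC1. The comparison asks how loss of Tsc1 changes the transcripts of these cells. Each genotype had 1 library, so no difference below has a replicate check, and the intervals cover counting error only. After filtering, the control library held 2042 cells with a median of 10613 UMIs and 3099.5 genes per cell. The KO library held 1936 cells with a median of 14928.5 UMIs and 3754.5 genes, a depth 1.41 times that of the control. The median mitochondrial share was 4.59% in the control and 5.72% in the KO library.

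Tsc1 (ENSMUSG00000026812, chromosome 2, 28641228 to 28691167, mm10) had 202 UMIs in control cells and 264 in KO cells. This was 9.42 CPM (8.16 to 10.8) against 8.55 CPM (7.55 to 9.65), a ratio of 0.908 (0.753 to 1.10). Droplet libraries count a tag from the end of a transcript, which can lie outside the deleted part of the gene. The counts of Tsc1 therefore do not check the genotype labels. Tsc2, the gene of the partner tuberin, had 16.5 CPM in the eGFP-positive control cells and 26.9 CPM in the eGFP-positive KO cells, a ratio of 1.63 (1.43 to 1.85).

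The reporter separated the cells. Of the 12 clusters, 7 held eGFP at 2940 to 5873 CPM and 5 held it at 0 to 84.5 CPM. The eGFP-positive clusters held 1703 control cells (83.4% of kept cells) and 1925 KO cells (99.4%). Their eGFP level was 5641 CPM in the control and 3588 CPM in the KO library. No tdTomato UMI was counted, which allows up to 0.140 CPM in the control and 0.0972 CPM in the KO library. The eGFP-negative clusters held 339 control cells, 16.6% (15.0 to 18.3), and 11 KO cells, 0.568% (0.284 to 1.01). Both libraries are labelled male. Y-linked genes (Ddx3y, Eif2s3y, Kdm5d and Uty) had 3287 UMIs in eGFP-positive control cells and 4498 in eGFP-positive KO cells, and 0 in the eGFP-negative cells of either library. Xist, the RNA of the inactive X chromosome in female cells (chromosome X, 103460366 to 103483254), had 1449 UMIs in the eGFP-negative control cells and 68 in the eGFP-negative KO cells. It was found in 304 of 339 and in 11 of 11 of these cells, against 4 of 1703 and 4 of 1925 eGFP-positive cells. Cluster 12 had 0 eGFP UMIs and 15 Xist UMIs.

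**Figure D1:**
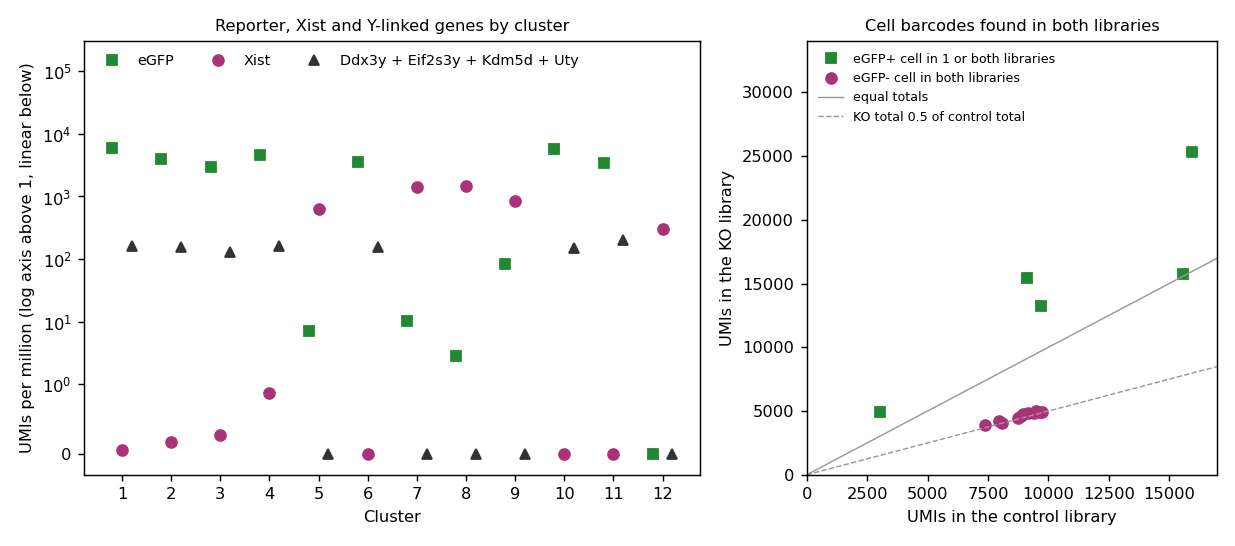
Left, CPM of eGFP, Xist and the sum of 4 Y-linked genes in each of the 12 clusters, both libraries summed, on an axis that is logarithmic above 1 and linear below. Right, UMI totals of the 16 cell barcodes found in both libraries, with lines at equal totals and at a KO total of 0.5 of the control total. The 11 barcodes that were eGFP-negative in both libraries had KO totals of 0.504 to 0.530 of the control totals.

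The eGFP-negative clusters carried immune markers. Cluster 5 was macrophage-like, led by Lyz2, Tyrobp and Fcer1g, and held 101 control cells and 0 KO cells. Clusters 8 and 9 were lymphocyte-like, led by the B cell genes Cd79a, Cd79b and Ms4a1 in cluster 8 and by Gzma and Nkg7 of cytotoxic cells in cluster 9. They held 82 and 65 control cells, and 4 and 0 KO cells. Cluster 12 was neutrophil-like, led by S100a8 and S100a9, with 7 control and 2 KO cells. Cluster 7, led by the class II antigen presentation genes H2-Aa and Cd74, met no naming rule and held 84 control and 5 KO cells.

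Of the 12 clusters, 11 drew at least 80% of their cells from 1 library, so a cluster may stand for its library as much as for a cell state. SMC-like clusters were cluster 1 (1325 control and 4 KO cells) and clusters 2, 6 and 11 (1203, 100 and 22 KO cells, with 1, 0 and 0 control cells). Cluster 3 held 593 KO cells, 30.6% of that library (28.6 to 32.7), and 2 control cells. Its leading genes were Spp1, Cytl1, Dcn, Lum, Igf1 and Vcam1, of which Dcn and Lum are fibroblast markers, and it stayed unnamed. Cluster 4 held 340 control cells, 16.7% (15.1 to 18.3), and 3 KO cells. It was led by Rgs5 and by homeobox genes (Prrx2, Msx2, Dlx5, Dlx6) and stayed unnamed, as did cluster 10, led by Des, with 35 control cells. Cluster 6 shared high Dlx5 with cluster 4, at 124 CPM against 140 CPM, where clusters 1, 2 and 3 had 4.18, 2.93 and 9.19 CPM.

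**Figure D2:**
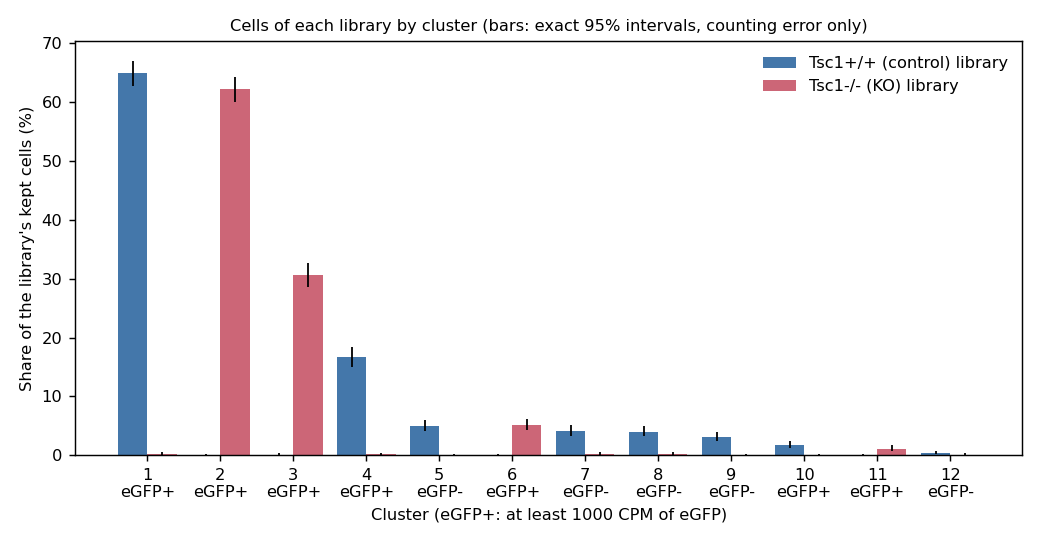
Share of each library's kept cells in each of the 12 clusters, with exact binomial 95% intervals for counting error. Control cells lie mainly in clusters 1 and 4 and KO cells in clusters 2 and 3, and clusters below the 1000 CPM limit for eGFP are marked eGFP-.

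Over all kept cells, Spp1, Gpx3 and Gpnmb were far higher in the KO library, and Ctss and Lyz2 far lower. Of 3016 genes at 50 CPM or more, 370 were at least 1.5 times higher and 390 at least 1.5 times lower in the KO library. Gpx3, a secreted glutathione peroxidase, was 403 times higher (333 to 494), Spp1 (osteopontin) 728 times (396 to 1518) and Gpnmb, a lysosomal and melanosomal membrane glycoprotein, 112 times (81.7 to 159). The 12 smallest ratios were all genes of the eGFP-negative clusters. Ctss, a lysosomal protease of antigen-presenting cells, was 82.3 times lower, and Lyz2 (lysozyme of myeloid cells) had 767 CPM in the control and 9.85 CPM in the KO library. Plac8, Gzma, Tyrobp, Fcer1g, Coro1a, AW112010, Cd52, Cd74 and H2-Aa were between 24.9 and 69.4 times lower, and Xist 28.3 times. The SMC contractile list had a median log2 ratio of -0.90, with 20 of 27 members lower and 0 higher. The lysosome and CLEAR network list had a median of 0.71, with 29 of 53 measured members higher and 2 lower. The antigen presentation and interferon list had a median of 0.03 with 7 members higher and 7 lower, which became 0.96 with 12 higher and 0 lower of 19 in the eGFP-positive clusters. The control library carried 16.6% eGFP-negative cells against 0.568% in the KO library, so the values that follow are for eGFP-positive clusters, a population added after the data were seen.

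Within the eGFP-positive clusters, 364 of 3022 genes were higher and 428 lower in the KO library, at a median depth of 11643 UMIs in control and 14994 in KO cells. Levels given as 1 CPM value against another are the control first and the KO library second. Of the 370 higher and 390 lower genes of all kept cells, 336 and 352 were listed here too. The largest difference was in Spp1, a secreted phosphoprotein of bone and of inflamed vessels (chromosome 5, 104435118 to 104441050). It had 0 control UMIs and 10474 KO UMIs, or 340 CPM, at least 2275-fold higher. Gpx3 (chromosome 11, 54902453 to 54910377) had 4.68 against 1958 CPM, a ratio of 418 (342 to 518). Ahsg, which encodes fetuin-A, a plasma inhibitor of calcification made chiefly by the liver, had 2 control UMIs and 75.1 CPM in the KO library, a ratio of 754 (208 to 6227). Its neighbour Fetub (chromosome 16, 22918334 to 22939778) was 146 times higher (92.3 to 247). Ptgds, which makes prostaglandin D2, was 171 times higher and Slco2a1, a prostaglandin transporter, 75.6 times. Cytl1, a secreted protein of cartilage, was 136 times higher, Aldh1a1, a retinaldehyde dehydrogenase, 83.2 times, and Gpm6a, a membrane glycoprotein of neurons, 44.3 times. Lum, a small proteoglycan of collagen fibrils, had 6.07 against 254 CPM, a ratio of 41.9 (35.0 to 50.5).

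Among abundant transcripts, Mgp, which encodes matrix Gla protein, an inhibitor of vascular calcification (chromosome 6, 136872435 to 136875823), had 5307 against 41045 CPM and was among the 5 most abundant genes of the KO library. Its ratio was 7.73 (7.69 to 7.78). Malat1, a nuclear noncoding RNA, was 1.59 times higher and Fth1, the ferritin heavy chain, 1.94 times, while Tmsb4x, an actin-binding peptide, had a ratio of 1.09.

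At the other end, Wif1, a secreted Wnt antagonist (chromosome 10, 121033960 to 121100650), had 169 CPM in the control and 7.24 CPM in the KO library, 23.4 times lower (20.4 to 26.9). Rgs5, a regulator of G protein signaling typical of mural cells, was 14.2 times lower, and 50.4% of thinned control cells against 7.82% of thinned KO cells had a UMI of it (unthinned 66.5% and 14.4%). In eGFP-negative control cells this share was 1.77% unthinned and 2.82% thinned. These cells lacked Y-linked UMIs, so they need not hold the free RNA of the control library, and they do not show that of the KO library. Their shares here and below are for comparison, and the background in KO cells was not measured. Rgs5 leads control cluster 4, which carried much of this difference: in cluster 2 against cluster 1 it was 5.12 times lower. Bdh1, a ketone body enzyme of mitochondria, was 10.4 times lower, Optc, a small proteoglycan, 9.68 times, Sema3d, a guidance cue, 7.75 times, and the homeobox gene Prrx2, which also leads cluster 4, 5.76 times. Mcam (CD146), an adhesion molecule of mural and endothelial cells, had 382 against 66.9 CPM and the imprinted noncoding RNA Meg3 620 against 110 CPM. Dlgap1, Scube3 and Fibin were between 5.47 and 5.61 times lower.

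The SMC contractile list, genes of the actomyosin apparatus and its regulators, had a median log2 ratio of -0.99 at percentile 0 of 10000 random lists. Of its 27 members 24 were lower and 0 higher. Actg2, gamma smooth muscle actin, was 5.12 times lower, Ppp1r14a, an inhibitor of myosin phosphatase, 4.44 times, and Des, the intermediate filament desmin, had a ratio of 0.238. Cnn1, which encodes calponin (chromosome 9, 22099216 to 22109630), had 2429 against 608 CPM, and the smooth muscle myosin gene Myh11 (chromosome 16, 14194535 to 14291372) 2503 against 846 CPM. Acta2, smooth muscle actin, the most abundant of the list, had 20898 against 11260 CPM, a ratio of 0.539 (0.536 to 0.541). Myocd, the coactivator that drives this program, had a ratio of 0.644 (0.595 to 0.698). After thinning, 99.9% of 1608 control cells and 69.1% of 1905 KO cells had a Cnn1 UMI (unthinned 99.9% and 85.5%). For comparison, 3.24% of the eGFP-negative control cells, with a median depth of 3776 UMIs, had one unthinned, and 2.82% of the 71 deep enough to thin.

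Of 28 dissociation stress and immediate early genes, 11 were lower and 0 higher, with a median of -0.39. In cluster 6 against cluster 4 this list had 4 members lower and 4 higher, with a median of 0.09. Hspa1a, an inducible heat shock protein, had 1168 against 259 CPM, Hspa1b was 3.25 times lower and Fos 2.02 times lower, while Zfp36 had a ratio of 1.37. Mitochondrially encoded genes had a median of 0.19 with 0 of 13 members past 1.5-fold.

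Lysosomal genes were higher as a group. The lysosome and CLEAR network list, many of whose members are targets of the MiT family of transcription factors, had a median of 0.70 (percentile 100), with 30 of 52 members higher and 1 lower. Gpnmb (chromosome 6, 49036546 to 49070929) had 1.84 against 199 CPM, a ratio of 108 (78.4 to 154). A Gpnmb UMI was found in 0.746% of thinned control cells and 52.1% of thinned KO cells (unthinned 1.47% and 76.7%), against 0.295% of unthinned and 1.41% of thinned eGFP-negative control cells. Rragd, a GTPase that couples amino acids to mTORC1, was 28.7 times higher (18.1 to 48.8). The enzymes Hexa and Lipa, which degrade gangliosides and lipid esters, were 3.37 and 3.27 times higher, and the cholesterol carrier Npc2 2.97 times. The membrane proteins Lamp2 and Cd63 were 2.42 and 2.29 times higher. Ctsk, a collagen-degrading cathepsin, had 7.67 against 24.1 CPM, while Ctsf had a ratio of 0.512 (0.466 to 0.561) and Ctsb 1.02. Among the MiT factors, Tfe3 was 1.70 times higher, Tfeb 2.09 times lower and Mitf had a ratio of 1.38, with a list median of 0.46 over 3 measured members. The melanocytic and osteoclast MITF targets, 7 measured, had a median of 1.65 (percentile 100) with 6 higher and 0 lower. They included Acp5, the tartrate-resistant phosphatase of osteoclasts, with 4 control UMIs and 13.4 CPM in the KO library, a ratio of 67.5 (26.1 to 249). This list shares Gpnmb, Ctsk and Atp6v0d2 with the lysosome list, so it is not a separate group of genes. The autophagy list had a median of 0.21 with 5 of 17 higher and 1 lower, led by Gabarapl1 (2.78) and Gabarap (1.67), with the cargo receptor Sqstm1 at 1.64.

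**Figure D3:**
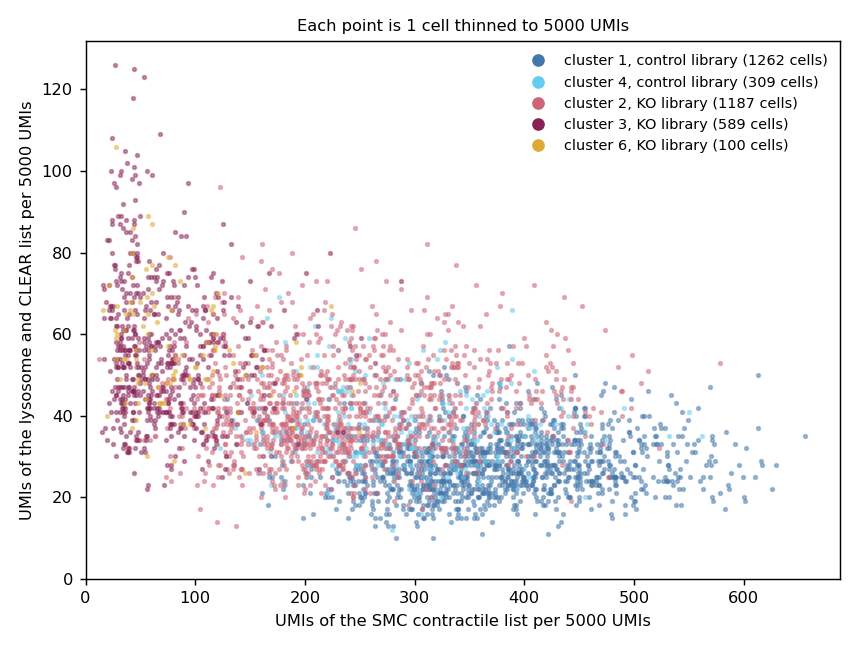
UMIs of the lysosome list against UMIs of the contractile list in each cell after thinning to 5000 UMIs, for clusters 1 and 4 of the control library and clusters 2, 3 and 6 of the KO library. Median contractile UMIs are 373 in cluster 1, 227 in cluster 2 and 62 in cluster 3, and median lysosome UMIs are 27, 41 and 53. For clusters 4 and 6 the contractile medians are 260 and 73, and the lysosome medians 36 and 54. Control cluster 4 thus lies nearer to KO cluster 2 than control cluster 1 does.

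Genes of modulated SMCs and of bone and cartilage were mostly higher, with a median of 2.33 (percentile 100) and 12 of 17 measured members higher and 2 lower. The list has 25 members, and the bootstrap range of the median over measured members was wide, 0.07 to 5.23. Besides Spp1 and Cytl1, the adhesion molecule Vcam1, also a member of the inflammation list, had 12.5 against 472 CPM, a ratio of 37.6 (33.2 to 42.8). Tnfrsf11b (osteoprotegerin), a decoy receptor that limits osteoclast formation, was 11.4 times higher, Lgals3 (galectin-3) 9.67 times, Timp1, an inhibitor of matrix proteases, 6.49 times, and Ank, a pyrophosphate transporter, 5.03 times. Msx2, another leading gene of cluster 4, was 9.21 times lower and Acan, the cartilage proteoglycan aggrecan, 1.70 times lower. A Vcam1 UMI was found in 3.42% of thinned control and 45.4% of thinned KO cells (unthinned 6.69% and 66.4%), and in 1.18% of unthinned and 2.82% of thinned eGFP-negative control cells.

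Matrix genes went both ways. The elastic fiber and matrix list had a median of -0.27 (percentile 0.850), with 15 of 38 members lower and 7 higher. Eln (elastin) had 2791 against 1211 CPM, the microfibril gene Mfap5 was 4.76 times lower, Vcan, the proteoglycan versican, 5.30 times lower and Col6a2 4.28 times lower. On the higher side were Col8a1 (33.6), the small proteoglycan Dcn (15.5) and Mgp, and Thbs1 (thrombospondin 1) had 15.9 against 175 CPM. Among proteases and inhibitors the median was 0.07, with 8 of 22 higher and 5 lower: the gelatinase Mmp2 was 7.82 times higher and Timp4 4.34 times, and Mmp17 was 3.19 times lower.

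Inflammation genes had a median of 1.74 (percentile 100), with 10 of 17 higher and 2 lower. This rested on members of low level: with a minimum of 50 CPM for members the median was -0.00584, and without cluster 3 it was 0.17. Icam1, an adhesion molecule for leukocytes, was 30.3 times higher (19.5 to 49.8), Cx3cl1 8.37 times and the chemokine Cxcl1 5.72 times, while Ptgs2 was 1.69 times lower and Ptgis, prostacyclin synthase, 1.74 times lower. In the antigen presentation and interferon list, the interferon-induced Ifit3 and Ifit1 were 10.9 and 9.37 times higher, and B2m, the light chain of class I molecules, 2.11 times. Phagocytosis and efferocytosis genes had a median of 0.42 (percentile 99.9) with 6 of 17 higher and 1 lower. Apoe, the lipid carrier apolipoprotein E (chromosome 7, 19696109 to 19699188), had 150 against 3508 CPM, a ratio of 23.3 (22.5 to 24.2). Mertk, a receptor for apoptotic cells, had a ratio of 0.726.

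Signaling lists were mixed. SMC growth factor and vasoactive receptors had a median of 0.01 with 8 of 26 higher and 6 lower: Igf1 was 39.1 times and Igfbp5 17.6 times higher, and Gucy1b3, a subunit of the nitric oxide receptor, 2.80 times lower. TGF-beta signaling and targets had a median of 0.08 with 5 of 23 higher and 6 lower, with Tgfb1 at 2.27 and Bambi, a decoy receptor, 4.56 times lower. The mTOR pathway components had a median of 0.17 with 5 of 24 higher and 2 lower. Genes of aortic position had a median of -0.19 with 0 of 13 higher and 2 lower, Hoxb2 at a ratio of 0.414 and Hoxa3 at 0.574.

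**Figure D4:**
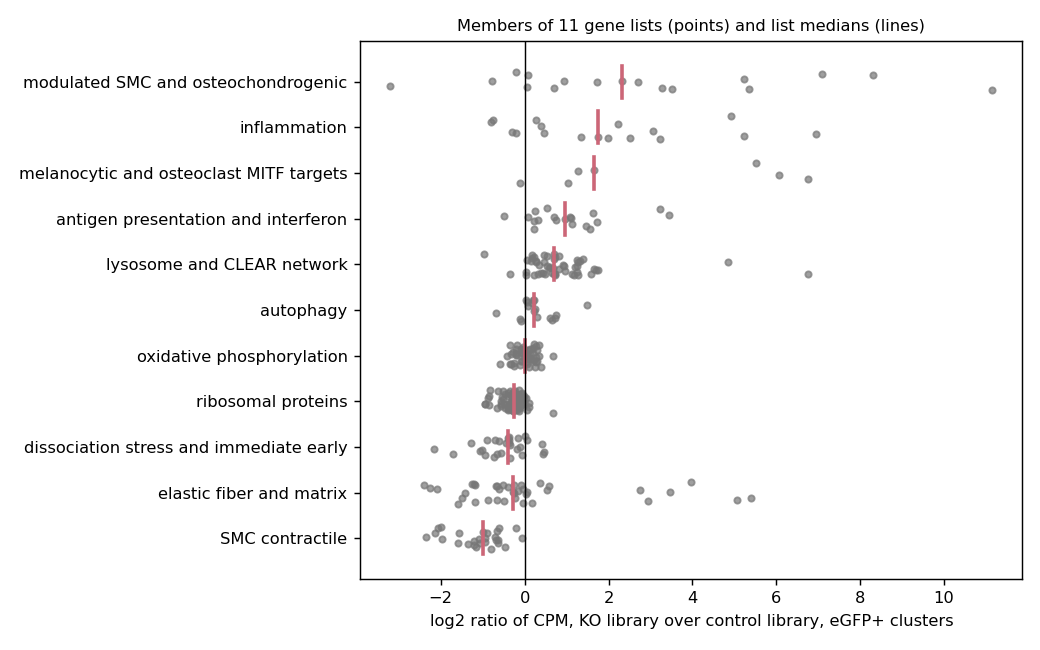
Log2 ratio of CPM, KO over control library, of each member (points) of 11 gene lists in the eGFP-positive clusters, with list medians as lines. Members with 0 control UMIs are drawn at their lower bound, and medians run from -0.99 for the contractile list to 2.33 for the list of modulated SMC genes.

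The SMC-like clusters (cluster 1 for the control and clusters 2, 6 and 11 for the KO library) are part of the eGFP-positive clusters. Within this part the contractile and lysosomal differences remained. Of 2982 genes 328 were higher and 333 lower, and 288 and 315 of these were also listed in the eGFP-positive clusters. Class boundaries left out cluster 3 (30.6% of KO cells) and clusters 4 and 10 (16.7% and 1.71% of control cells). Of the clusters with high Dlx5, KO cluster 6 was thus kept and control cluster 4 left out, so the sides were not like for like. Median contractile UMIs per thinned cell were 260 in control cluster 4, 227 in KO cluster 2 and 73 in KO cluster 6. The missing name therefore does not mean that cluster 4 lacked contractile transcripts. Gpx3 had 0.799 against 1451 CPM, a ratio of 1816 (1062 to 3410), and Gpnmb 1.60 against 156 CPM. Other large ratios were those of Fetub (141), Ptgds (95.4), Slco2a1 (62.2), the cadherin Cdh11 (37.2), Apoe (31.9), Gpm6a (30.7), the potassium channel Kcnk3 (25.7), Lum (25.3), Tmem176b (14.7) and the growth factor Mdk (14.1). Wif1 was 27.6 times lower, Bdh1 10.3 times and Optc 7.38 times. Galnt16, Sema3d, Meg3, Dlgap1, Pdlim4, Mcam, Dusp10 and Rgs2 were 4.37 to 5.95 times lower. The contractile list had a median of -0.72, with 16 of 27 lower and 0 higher: Acta2 had 22434 against 15181 CPM, while Cnn1 was 2.80 times lower. The lysosome list had a median of 0.69 with 28 of 52 higher and 1 lower. The modulated SMC list had a median of 1.63 and the inflammation list 0.28, and in cluster 2 against cluster 1 these were 0.83, with 8 of 13 members higher, and 0.22.

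Because clusters divided by library, 3 pairs of clusters were set side by side by number. List medians hold all measured members. Without Ppp1r14a, a leading gene of cluster 1, the contractile median was -0.67 for clusters 2 and 1 and -1.95 for clusters 3 and 1. In cluster 2 of the KO against cluster 1 of the control library, the largest cluster of each, Gpnmb was 110 times higher (72.3 to 175), Apoe 30.9 times and Hexa 2.86 times, and the lysosome list had a median of 0.63. Myh11 was 2.20 times lower and the contractile median was -0.69, with 15 of 27 members lower. In cluster 3 against cluster 1, all 27 contractile members were lower, with a median of -2.00. Cnn1 had 2465 against 109 CPM and Acta2 22439 against 4099 CPM, and 30.6% of thinned cluster 3 cells had a Cnn1 UMI and 64.9% a Myh11 UMI. Unthinned, at a median depth of 17413 UMIs, these shares were 65.6% and 88.7%, and the Myh11 share in eGFP-negative control cells was 5.31% unthinned and 8.45% thinned. The lysosome median was 0.87, with Hexa 5.14 times and Npc2 4.68 times higher. Cluster 6 against cluster 4, both with high Dlx5, gave a contractile median of -1.52 with 25 of 26 lower, and a lysosome median of 0.62 with 28 of 52 higher. This pair also differed in the genes of aortic position, with a median of -0.35 and 5 of 12 lower. The CPM of cluster 2 was 53.1% of that of cluster 3 for Gpnmb, 51.8% for Apoe and 38.4% for Gpx3. For leading genes of cluster 3 it was 3.55% for Cytl1, 4.68% for Dcn, 5.45% for Spp1, 5.80% for Lum, 5.92% for Igf1, 6.04% for Ahsg and 6.40% for Aldh1a1, and 10.3% for Vcam1 and 12.4% for Cp. Free RNA of cluster 3 in the droplets of cluster 2 would give its genes a like low ratio, and expression of these genes in cluster 2 was not separated from it.

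In the authors' deposited table of cluster averages, clusters 0 to 4 hold eGFP in the columns of both libraries, and Gpnmb was higher in the KO column of each. The control column of cluster 3 in the authors' deposited table had eGFP at 9.73, Acta2 at 33.2, Ptprc at 3.25 and Xist at 10.1 mean counts per 10000. That column lay closest to the lymphocyte-like cluster 9 here, but at a Pearson correlation of only 0.890, so the match does not name its cells. The KO column of cluster 3 in the authors' deposited table lay closest to the SMC-like cluster 2, at 0.995. Gpnmb was 1.20, 0.655, 2.67, 1.74 and 1.04 in the KO columns of clusters 0, 1, 2, 3 and 4 of the authors' deposited table, and 0.0143, 0.00979, 0, 0 and 0.0495 in the control columns. Myh11 was 13.2, 11.04, 3.41 and 7.99 in the KO columns of clusters 0, 1, 2 and 4 of the authors' deposited table and 24.4, 21.7, 4.64 and 17.3 in the control columns. In cluster 3 of the authors' deposited table, whose columns thus hold unlike cells, Myh11 was 7.94, Acta2 141, Lum 1.17 and Dcn 1.89 in the KO column, and 3.83, 33.2, 0 and 0.0687 in the control column. Acta2 was 243, 204, 46.1 and 60.1 in the KO columns of clusters 0, 1, 2 and 4 of the authors' deposited table and 228, 196, 76.0 and 117.5 in the control columns, so it was lower in clusters 2 and 4 and not in clusters 0 and 1. In the same order, these KO columns held 9505, 10750, 14473 and 6888 genes above 0, and the control columns 14310, 13753, 6053 and 13263. The column with fewer genes in each pair may average few cells. For the authors' cluster 4, the control column lay closest to cluster 4 here, at a Pearson correlation of 0.999, and the KO column to cluster 6, at 0.929. These pairs therefore do not show how much Acta2 differed between like cells. Lum was 0.545, 0.521, 7.93 and 0 in the KO columns of clusters 0, 1, 2 and 4 of the authors' deposited table and 0.0191, 0.136, 13.01 and 0 in the control columns. Dcn was 1.16, 0.819, 9.71 and 0.480 in the KO columns of clusters 0, 1, 2 and 4 of the authors' deposited table and 0.0482, 0.746, 25.4 and 0.0251 in the control columns, so both genes were lower in the KO column of cluster 2, and higher in those of clusters 0 and 1. The columns of cluster 2 in the authors' deposited table need not hold like cells. Its control column lay closest to cluster 4 here, at a Pearson correlation of only 0.900, and its KO column to cluster 3. The lower Lum and Dcn there therefore do not show a fall within 1 cell type. The number of cells behind each column is not given in the sources used here, so these averages carry no interval. Xist was 10.1, 6.85, 15.0, 12.9 and 7.83 in the control columns of the authors' clusters 3, 5, 6, 7 and 8, and 16.5 and 15.2 in the KO columns of clusters 6 and 7, in the authors' deposited table. It was 0.136 and 0.0602 in the control columns of clusters 0 and 1 of the authors' deposited table.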

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

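Of the tests here, the counts of Y-linked UMIs and of barcodes shared by eGFP-positive cells were chosen after their results were seen, and so were the UMI totals and ranks of the shared barcodes. The count of barcodes shared by eGFP-negative cells was predicted before it was made, when the total of 16 barcodes found in both libraries was known.

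The eGFP-negative clusters were flagged because they carry a signal that neither the sort nor the labels would give: 1449 Xist UMIs in the control library and 68 in the KO library, in libraries labelled male and sorted for GFP. The 11 cell barcodes that were eGFP-negative cells in both libraries were flagged later, once counted as a test of the Xist signal. If the eGFP-negative cells were cells of the labelled male mice that passed the sort, 223 UMIs of Y-linked genes would be expected in the control library at the rate of its eGFP-positive cells, and 0 were counted, which argues against that explanation. If reads of the control library had passed to the KO library, 55.3 control eGFP-positive cells would share a barcode with a KO cell at the rate of the eGFP-negative cells, and 4 did, which argues against that explanation too. Reads of 1 outside library split over both libraries by exchanged sample indices remain a candidate explanation: all 11 eGFP-negative KO cells shared their barcode with an eGFP-negative control cell of the same cluster, where 0.0286 were expected at the rate of eGFP-positive KO cells, each KO total was 0.504 to 0.530 of the control total, and the control copies ranked at or above percentile 96.5 by UMIs among the 339 eGFP-negative control cells. Female cells mixed in before the sort stay open as an untested source of part of the cells, and no biological explanation was tested, since the design names no female group. Such cells would have had to pass a sort for GFP, while the 339 eGFP-negative control cells held 25 eGFP UMIs.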

How the results depend on the processing

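The tests with eGFP-positive clusters only, without cluster 3, with pairs of clusters, with cells matched on UMI totals or on Hspa1a and Hspa1b and with cells lacking Hspa1a and Hspa1b were chosen after the data were seen. No paired analysis was possible because each group had 1 library, both numbered replicate 1 only, and there was no test. Counts of listed genes depended on the minimum level and the fold: higher and lower in the KO library were 747 and 677 at 20 CPM, 103 and 159 at 200 CPM, 2915 and 3013 with no minimum, and 177 and 178 at 2-fold for all kept cells. For eGFP-positive clusters these were 739 and 700, 100 and 173, 3186 and 2846, and 174 and 180, and for SMC-like clusters 705 and 515, 87 and 140, 3199 and 1967, and 146 and 139. For the minimum levels the number of eligible genes, and for 2-fold the stricter fold, explain these moves by construction. With clusters 3 and 1 in place of eGFP-positive clusters, 549 genes were higher, where the cause was not tested, and the other settings run kept the counts within 1.5 times. Under TMM the share of higher among listed genes in SMC-like clusters was 40.6% against 49.6%. The contractile median kept its sign in every setting: it was -1.25, -1.37 and -1.003 under the stricter cell filter for all kept cells, eGFP-positive and SMC-like clusters, and, for eGFP-positive clusters, -0.68 without cluster 3, -0.69 for clusters 2 and 1, -2.00 for clusters 3 and 1, -1.52 for clusters 6 and 4, -0.66 and -1.99 for clusters 2 and 1 and clusters 3 and 1 matched on thinned Hspa1a and Hspa1b UMIs, and -1.21 in cells with no thinned Hspa1a or Hspa1b UMI, where cluster 3 made up 45.1% of KO cells in place of 30.8%. The lysosome median moved beyond its bootstrap range for clusters 3 and 1 only, to 0.87 and, matched on Hspa1a and Hspa1b, 0.90. The inflammation median reversed when members needed 50 CPM, to -0.0672 for all kept cells and -0.00584 for eGFP-positive clusters, with fewer members measured. Acp5 over all kept cells reversed to -0.40 with equal weight per cell, and Retnlg to 0.60 in thinned cells. Immune markers with few UMIs also reversed: in eGFP-positive clusters Cd79b (-0.24, thinned), Laptm5 (0.12) and Nkg7 (0.10, both without doublets) and Retnlg (-0.32, stricter filter), and in SMC-like clusters Cd79b (-0.0560) and Fcer1g (0.18, both thinned), Csf3r (-0.0722, stricter filter, and -0.26, equal weight), Laptm5 (0.13) and Nkg7 (0.13, both without doublets), and Retnlg (-0.66, looser filter, and -0.0722, stricter filter). The cause of these reversals was not tested. Of 12 clusters 11 drew 80% or more of their cells from 1 library, and 9 of 10, 16 of 18, 11 of 11 and 10 of 10 did at resolution 0.3 and 1.0, with 15 components and on thinned cells. Thinning to 2500 UMIs lowered shares of cells with a UMI: the Gpnmb share in KO cells was 34.3%. Of the list medians, 359, 492 and 283 values over all settings for all kept cells, eGFP-positive and SMC-like clusters stayed within the main bootstrap range, and 14, 44 and 9 left it without reversing, the contractile and lysosome values above among them. In eGFP-positive clusters the others included autophagy (0.63 with members at 50 CPM), inflammation (0.17 without cluster 3), sterol synthesis (0.02 in cells matched on UMI totals), ATF4 targets (-0.14 for clusters 6 and 4) and dissociation stress (0.09 for clusters 6 and 4). Over all kept cells, antigen presentation and interferon was -0.64 with equal weight per cell, and the ribosomal list moved in 6 settings, to between -0.55 and -0.26. The mitochondrially encoded median in eGFP-positive clusters changed sign within its range, from 0.19 to -0.16 under the stricter cell filter. Of the single genes, 589, 449 and 448 values left the main counting interval without reversing a listed change. Depth limits the eGFP-negative KO cells most, where 3 counts equal 59.3 CPM.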

Other observations

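The tests with cells matched on UMI totals, with clusters 2 and 1, with clusters 6 and 4 and with cells matched on Hspa1a and Hspa1b were chosen after the data were seen, as were the contractile and lysosome lists for weighing.

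The following lists were not described above, and their values are for the eGFP-positive clusters. NRF2 targets had a median log2 ratio of 0.19 (percentile 95.7), with 6 of 16 members higher and 2 lower. Ftl1, the ferritin light chain that stores iron, had 1065 CPM in the control and 5856 CPM in the KO library, Hmox1, which frees iron from heme, was 4.76 times higher and Txnrd1, thioredoxin reductase, 2.12 times, while Nqo1 was 1.63 times lower. Fatty acid synthesis genes had a median of 0.48 (percentile 99.4) with 3 of 11 higher and 0 lower, among them the desaturases Scd2 (2.35) and Scd1 (1.74). Sterol synthesis genes had a median of 0.19 with 3 of 19 higher and 0 lower, with Hmgcs1 at 0.879, and the median was 0.02 in cells matched on UMI totals. ATF4 targets and amino acid synthesis genes had a median of 0.37 (percentile 99.8) with 8 of 21 higher and 1 lower, led by the stress protein Nupr1 (2.38) and the serine synthesis enzyme Phgdh (1.98), while Atf4 itself had a ratio of 0.815. In clusters 6 and 4 this list went the other way, with a median of -0.14, 5 of 22 higher and 3 lower. The unfolded protein response list had a median of 0.18 with 3 of 19 higher and 0 lower, Sdf2l1 at 3.85. Glycolysis and pentose phosphate genes had a median of 0.12 with 2 of 21 higher, Pgd at 2.06, and 2 lower, Pfkm at 0.471. Translation factors had a median of -0.22 with 0 of 24 higher and 1 lower, oxidative phosphorylation genes 0.02 with 1 of 50 higher and 0 lower, and ribosomal proteins -0.26 with 1 of 82 higher and 8 lower.

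Cell cycle genes went apart from each other, with a median of 0.29 and 5 of 14 higher and 1 lower. In SMC-like clusters the median was -0.00142 with 3 of 12 higher, and in clusters 3 and 1 it was 0.83 with 13 of 19 higher and 1 lower. Clusters 2 and 1, with the same control cells, had 11 members measured, 3 of them higher. The members measured only for clusters 3 and 1 passed the 5 CPM minimum through their level in cluster 3. These medians therefore rest on unlike sets of members and do not show where the rise lay. Ccnd1, the G1 cyclin D1, had 4 control UMIs and 28.0 CPM in the KO library, a ratio of 141 (54.7 to 517), and its partner kinase Cdk4 was 1.54 times higher. The inhibitor gene Cdkn1a (p21) was 1.71 times higher, and Cdkn1c 1.61 times lower. By cluster, Ccnd1 was 58.2 CPM in cluster 3, 9.84 CPM in cluster 2 and 0.185 CPM in cluster 1.

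The lysosome and CLEAR network list lay higher in the KO library. If more UMIs per cell in the KO library were the whole cause, its median would lie close to that of all genes among cells matched on UMI totals, and it was 0.63 there (1284 cells per library), while the pair of clusters 2 and 1, which leaves out cluster 3, also gave 0.63. With cells matched on thinned UMIs of Hspa1a and Hspa1b it was 0.58 for clusters 2 and 1 (746 cells per library) and 0.90 for clusters 3 and 1 (354 cells per library). For clusters 2 and 1 this argues against a different heat shock response to tissue digestion as the whole cause. The matching was not complete, since Hspa1a kept ratios of 0.840 and 0.584 over all UMIs of these cells. The dissociation stress median after matching was -0.09 for clusters 2 and 1 and -0.35 for clusters 3 and 1, so the second pair does not decide. A different mix of aortic positions stays open: clusters 6 and 4, both with high Dlx5, gave 0.62, but their own aortic position list had a median of -0.35 with 5 of 12 members lower, so this pair does not hold position fixed. The library or animal instead of genotype cannot be told apart from the KO itself, since there was 1 library per genotype. An effect of Tsc1 loss is 1 candidate explanation among these.

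The SMC contractile list lay lower in the KO library. Cells matched on UMI totals gave a median of -0.99, which argues against depth as the whole cause. Cells matched on thinned UMIs of Hspa1a and Hspa1b gave -0.66 for clusters 2 and 1 and -1.99 for clusters 3 and 1, against -0.69 and -2.00 unmatched. For clusters 2 and 1 this argues against the heat shock response as the whole cause. For clusters 3 and 1 the matching was partial: their dissociation stress median was -0.35 after it and -0.75 before, so that pair does not decide. Clusters 6 and 4 gave -1.52, but they differ in genes of aortic position, so the mix of positions stays open. How much rests on cluster 3 alone stays open: clusters 2 and 1 gave -0.69 with a bootstrap range over members of -0.85 to -0.41, which takes in -0.49, the size at which 50% of the difference would remain. The library or animal instead of genotype cannot be told apart from the KO either, with 1 library per genotype. Loss of contractile transcripts after Tsc1 deletion is 1 candidate explanation among these.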
